A study of Mus musculus with 12 samples.

How the data were processed

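RNA sequencing was analysed for 12 libraries of primary C57Bl6 mouse neurons in 4 groups of 3: OGD, OGD control, KA (100 µM) and KA control. Per the labels, total RNA was purified on RNeasy columns and libraries were made with a TruSeq RNA kit, which does not mark strand. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat 1.4.1 and HTSeq 0.6.1 were used with the mouse build mm10; settings and annotation are not given in the sources used here. The deposited table holds raw counts per gene symbol, whole numbers that the authors did not normalize, for 22899 genes. Its columns for the OGD experiment are headed with OGT where the sample titles read OGD; they were matched by name with this 1 letter different, and the table holds no other label to check them against.

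Gene symbols were matched to GENCODE M21, which is on the same build; 22516 matched, 963 of them through an older symbol, and 383 did not. Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr over the 4 groups (minimum count 10, minimum total 15), TMM normalization, and the quasi-likelihood test in one fit of the 4 group means over all 12 libraries, with 8 residual degrees of freedom. Contrasts were OGD against OGD control, KA against KA control, the difference of these responses, and KA control against OGD control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM scaled and given as mean ± SD of 3 libraries, and the SE of a log2 fold change comes from the test statistic. The common biological coefficient of variation was 0.0402.

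A total of 37 gene lists (pathways, receptor and channel families, stress responses and cell type markers) were fixed before the data were examined. Lists with at least 5 tested members (34 of 37) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of one comparison, and again with an estimated correlation. The list of mitochondrially encoded respiratory chain genes had none of its 13 genes in the table. The rotation test fry asks only whether a list moves one way on balance. Genes were named by a rule fixed beforehand. Per treatment comparison it took the 8 largest changes in each direction among called genes with a mean of at least 2 logCPM and no overlap between the groups' libraries, and up to 3 members with the smallest adjusted p from each list described (2 where none passed). It also took the 6 largest in each direction for the difference of responses, the 4 largest for the controls, and regardless of outcome Grik1 to Grik5, Gria1 to Gria4, Vegfa, Slc2a1, Pdk1, Ldha, Fos, Npas4, Arc and Bdnf.

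At these totals 1 count equals between 0.0473 and 0.0777 CPM, and a count of 0 allows up to 0.142 to 0.233 CPM (3 counts), covering counting error only. Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom from 1.49 to 6.19 over genes with at least 20 counts), so each library was counted once. Counts were simulated with each gene's mean over all 12 libraries, the real library sizes and a spread set by a trend on level. On these, the OGD comparison recovered 38% of genes changed 1.2-fold, 60% at 1.5-fold, 90% at 2-fold and 96% at 4-fold (12944 genes, 50 changed per size). The KA comparison recovered 42%, 76%, 90% and 98% (12922 genes). Unchanged genes made up 2 of the 144 calls for OGD and 12 of the 165 for KA. Far fewer genes were changed than were called in the data, so these shares need not hold there. A list raised 1.5-fold was called in each simulation, and 0 of 20 random lists were. Genes were simulated independently of each other, so this does not test lists whose members vary together.

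Some genes with several annotated transcripts have few or no counts in this table, while others, such as Lrrtm1, are well counted, which limits comparisons of level between genes. Vegfa, for example, with 18 of its 3523 exonic bases in no other transcript, has no count. Whether this also affects comparisons of one such gene between groups was not tested. Counts of calls were repeated on the 9385 tested genes with 1 annotated transcript, which leaves the genes with several transcripts out. Alternatives fixed beforehand were DESeq2 1.42.0, its size factors within edgeR, no count filter, a filter of 1 CPM in every library of a group, a block on the replicate number, fits of only the groups compared, and leaving out each library. Genes with 1 transcript and the removal of a trend on transcript length (12937 of 13139 tested genes had a length) were added after seeing the data. No sample or file was left out. Not every gene that the naming rule selects is reported here.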

Results

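Gene expression was measured by RNA sequencing in primary mouse neurons, cultured from C57Bl6 animals, after 2 forms of acute injury. Oxygen-glucose deprivation (OGD) removes oxygen and glucose together and is a culture model of ischaemia. Kainic acid (KA), an agonist of kainate and AMPA glutamate receptors, was added to the culture medium at 100 µM and is a model of excitotoxic injury. Each injury had its own untreated controls, so that the 12 libraries formed 4 groups of 3: OGD, OGD control, KA and KA control. The length of exposure and of any recovery is not given in the sources used here. Total counts per library ranged from 12873444 (KA replicate 3) to 21142267 (KA control replicate 2), and 13139 of the 22899 genes in the table had enough counts to be tested. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

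Against its own controls, OGD changed many genes by a small amount and lowered late activity-regulated genes as a group. Immediate early genes went both ways. Baz1a, a chromatin remodelling subunit that is also in the list of late activity-regulated genes, fell from 68.3 ± 3.28 CPM in OGD control to 22.6 ± 1.10 CPM in OGD (SD, n = 3 each; log2 fold change -1.60, SE 0.07, adjusted p = 1.26e-16). The genes that rose most included Slc16a9, a monocarboxylate transporter family member, at 4.47 ± 0.59 CPM in OGD and 1.87 ± 0.32 CPM in OGD control (log2 fold change 1.27, SE 0.17, adjusted p = 5.69e-07). Crebzf, a bZIP transcription factor, rose 2.33-fold and Gmppb, an enzyme of GDP-mannose synthesis, rose 2.20-fold. In total, 2315 genes were higher and 2694 lower in OGD (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), of which only 54 and 164 changed over 2-fold.

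Among the other genes with the largest falls after OGD were Nup210l (log2 fold change -1.80, SE 0.11), Fgf10 (-1.43, SE 0.09), Dtl (-1.42), Trim17 (-1.41), Dennd2c (-1.29), Rrad (-1.29) and Ism1 (-1.28). Hspa1a, an inducible heat-shock protein, rose to 11.4 ± 1.02 CPM from 4.84 ± 0.60 CPM; its near-identical neighbour Hspa1b can share its reads, so the value is uncertain. Dhtkd1, Srrm4os, A930013F10Rik and 3110057O12Rik also rose, by 1.12, 1.06, 0.99 and 0.99 on the log2 scale. Srrm4os lies antisense to Srrm4, and Gmppb overlaps Gm20529 on its own strand and Rnf123 on the other. The library kit does not mark strand, so reads of such pairs cannot be separated. Baz1a lies on chromosome 12 at 54892989 to 55014348 and Slc16a9 on chromosome 10 at 70245100 to 70285968 (mm10).

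Of 31 late activity-regulated genes tested, 24 fell and none rose after OGD, with a median log2 fold change of -0.29. Plk2 fell from 764 ± 35.8 to 471 ± 7 CPM and Nptx2, a synaptic pentraxin, from 310 ± 18.7 to 173 ± 19.6 CPM. Bdnf, the neurotrophin gene, was 40.1 ± 3.04 CPM in OGD control and 20.9 ± 1.51 CPM in OGD. Adjusted over the list alone, 27 fell and 1 rose. The list passed camera (adjusted p = 2.89e-18 with the preset correlation, adjusted p = 0.0121 with an estimated correlation). Set against KA control, where these genes were lower than in OGD control, 26 of 31 were higher in OGD and 3 lower (median 1.31). Immediate early genes, the first wave of transcription after stimulation, went both ways: 8 of 28 rose and 10 fell. Egr1 rose from 112 ± 7.61 to 194 ± 14.3 CPM and Btg2 from 116 ± 2.06 to 163 ± 3.56 CPM, while Ier5 fell (log2 fold change -0.79) and Npas4 fell (-0.31). Fos did not pass the test (1304 ± 44.0 CPM in OGD, 1215 ± 27.3 CPM in OGD control, adjusted p = 0.109). It passed without the count filter (adjusted p = 0.0351) and in a fit of these 6 libraries alone (adjusted p = 0.0137). Against KA control, 27 of 28 immediate early genes were higher in OGD (median 3.56).

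Markers of excitatory neurons were also lower after OGD. Among 15 markers of excitatory neurons, 10 fell and none rose (median -0.30; 12 fell and 1 rose adjusted over the list alone), and the list passed with both correlations (adjusted p = 9.53e-12 and, with an estimated correlation, adjusted p = 0.0285). Tbr1 and Fezf2, both cortical transcription factors, fell by 0.74 and 0.73 on the log2 scale. In OGD against KA control, 6 of the 15 markers were higher and 6 lower (median 0.004). Among 16 inhibitory markers 9 fell, led by Gad2, which makes GABA (439 ± 16.3 against 653 ± 7.61 CPM), and Sp9. Against KA control, 15 of these 16 were higher in OGD and 0 lower (median 1.17). Of 29 postsynaptic scaffold genes 14 fell and 1 rose, with Lrrtm1 lower by 0.88. Both lists passed with the preset correlation (adjusted p = 0.00186 and 0.00231) and not with an estimated one (adjusted p = 0.367 for each). Voltage-gated sodium and potassium channels (13 of 36 fell, 4 rose, among them Kcna1 and Kcnc4, both lower) had adjusted p = 0.0362, or adjusted p = 0.556 with an estimated correlation. Without OGD replicate 1 or replicate 3 that list missed the threshold (adjusted p = 0.074 and 0.0506). With a trend on transcript length removed, the scaffold list had adjusted p = 0.0831 and the channel list 0.279 (medians -0.09 and -0.01). Among genes with 1 annotated transcript, which are fewer, both had 0.0767 with medians of -0.14 and -0.07.

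Genes induced by low oxygen tended to rise after OGD, with 14 of 30 higher and 2 lower (median 0.11, adjusted p = 0.000311, or adjusted p = 0.386 with an estimated correlation). Narf rose from 61.1 ± 3.52 to 96.9 ± 2.56 CPM and P4ha1, a collagen prolyl hydroxylase subunit, by 0.62 on the log2 scale, whereas Stc2 fell by 0.51. Pdk1, a pyruvate dehydrogenase kinase, rose from 49.1 ± 3.99 to 72.0 ± 3.53 CPM, and Slc2a1, a glucose transporter, from 60.6 ± 5.80 to 77.0 ± 10.3 CPM. Vegfa had no counts in any library, which holds for some genes with several annotated transcripts and not for others, such as P4ha1. Ldha lay near the floor (1.39 and 0.75 CPM; adjusted p = 0.0313) and lost its call with DESeq2 (adjusted p = 0.111) and when any 1 library of either group other than OGD replicate 2 was left out, with adjusted p from 0.0676 to 0.124. Cholesterol synthesis genes were higher in 11 of 23 cases and lower in 4 (adjusted p = 0.0272, or adjusted p = 0.556 with an estimated correlation); Dhcr7 rose by 0.45 and Ebp fell by 0.53. Among genes with 1 annotated transcript, which are fewer, this list had adjusted p = 0.0709 and a median of 0.07, against 0.09 over all its genes. Targets of ATF4, the factor of the integrated stress response, fell in 12 of 31 cases and rose in 1, with Sesn2 lower by 0.47 and Slc7a1 by 0.28. That list had adjusted p = 0.0343, or adjusted p = 0.589 with an estimated correlation, and missed the threshold without OGD replicate 2 (adjusted p = 0.108) or OGD control replicate 1 (adjusted p = 0.103).

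Cytosolic ribosomal protein genes rose in 29 of 78 cases and nuclear-encoded respiratory chain genes in 20 of 73, and none of either fell. The changes were small, with medians of 0.10 for both; Rpl3 rose from 769 ± 10.6 to 898 ± 23.2 CPM and Ndufs7 from 60.0 ± 2.71 to 73.0 ± 4.93 CPM. Both lists passed with the preset correlation (adjusted p = 7.15e-05 and 0.000796) and missed the threshold with an estimated one (adjusted p = 0.718 for each). With the trend on transcript length removed, their medians were -0.0031 and -0.0039 and neither passed (adjusted p = 0.67 and 0.848).

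No other list passed camera after OGD. Glycolysis enzymes (6 of 18 rose, 1 fell), pro-apoptotic genes (7 of 22 rose, 1 fell), autophagy and lysosome genes (8 of 28 rose, 5 fell) and nuclear long non-coding RNAs of neurons (3 of 8 rose, 1 fell) had more members higher than lower, and p53 targets were even (7 of 26 rose, 7 fell). More members fell among heat-shock chaperones (7 of 20, 3 rose), ER chaperones (6 of 23, 3 rose), oxidative stress genes (6 of 23, 4 rose), axon injury genes (8 of 26, 2 rose) and general neuron markers (5 of 17, 2 rose). The same held for ionotropic glutamate receptors (5 of 23, 1 rose), GABA receptor subunits (5 of 14, none rose), metabotropic glutamate receptors (2 of 6), presynaptic genes (6 of 33, 3 rose), calcium handling genes (4 of 24, 3 rose), clock genes (3 of 12, 2 rose) and cell-cycle genes (4 of 21, 2 rose). Inflammatory genes (2 of 10 fell) and interferon-stimulated genes (1 of 12 rose, 1 fell) were mostly too low to test. Grik3, a kainate receptor subunit, fell from 227 ± 4.25 to 148 ± 7.46 CPM, and Gria2 rose by 0.33 on the log2 scale (adjusted p = 0.00338, or 0.0578 with DESeq2). Grik1, Grik2, Grik4, Grik5, Gria1 and Gria4 did not pass, with log2 fold changes from -0.17 (Grik1) to 0.26 (Gria1). Markers of astrocytes fell in 4 of 14 cases (adjusted p = 0.0642, 0.025 without OGD replicate 3 and 0.0473 without OGD control replicate 1), of oligodendrocytes in 2 of 7 and of fibroblasts and mural cells in 2 of 12; 1 of 9 microglial markers rose, and none of 3 endothelial or 4 blood and choroid plexus markers passed. Among genes with 1 annotated transcript, the pro-apoptotic and astrocyte lists passed (adjusted p = 0.0246 for each); over all genes each had adjusted p = 0.556 with an estimated correlation. Adjusted over the list alone, 10 of 36 lists had other counts, by at most 4 members.

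Immediate early genes rose after KA. Of 28 immediate early genes tested 27 rose and none fell, with a median log2 fold change of 4.05 (the same counts adjusted over the list alone; camera adjusted p = 1.39e-93, or adjusted p = 0.0043 with an estimated correlation). Set against OGD control, where these genes were higher than in KA control, the median in KA was 0.89. Fosb, an AP-1 subunit, rose from 13.4 ± 3.64 CPM in KA control to 1184 ± 89.1 CPM in KA (SD, n = 3 each; log2 fold change 6.45, SE 0.10, adjusted p = 4.22e-30). Npas4, an activity-dependent transcription factor, rose from 67.4 ± 5.13 to 2645 ± 138 CPM (log2 fold change 5.29, SE 0.06, adjusted p = 4.42e-32), and Fos from 82.4 ± 8.75 to 2579 ± 105 CPM. Klf4, Csrnp1, Gprc5a, Gem, Gadd45g and Egr2 completed the genes with the largest rises, at 6.12, 5.43, 5.41, 5.41, 5.27 and 5.13 on the log2 scale. Over all genes, 4622 were higher and 4936 lower in KA than in KA control, 1467 and 1304 of them by over 2-fold.

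**Figure D1:**
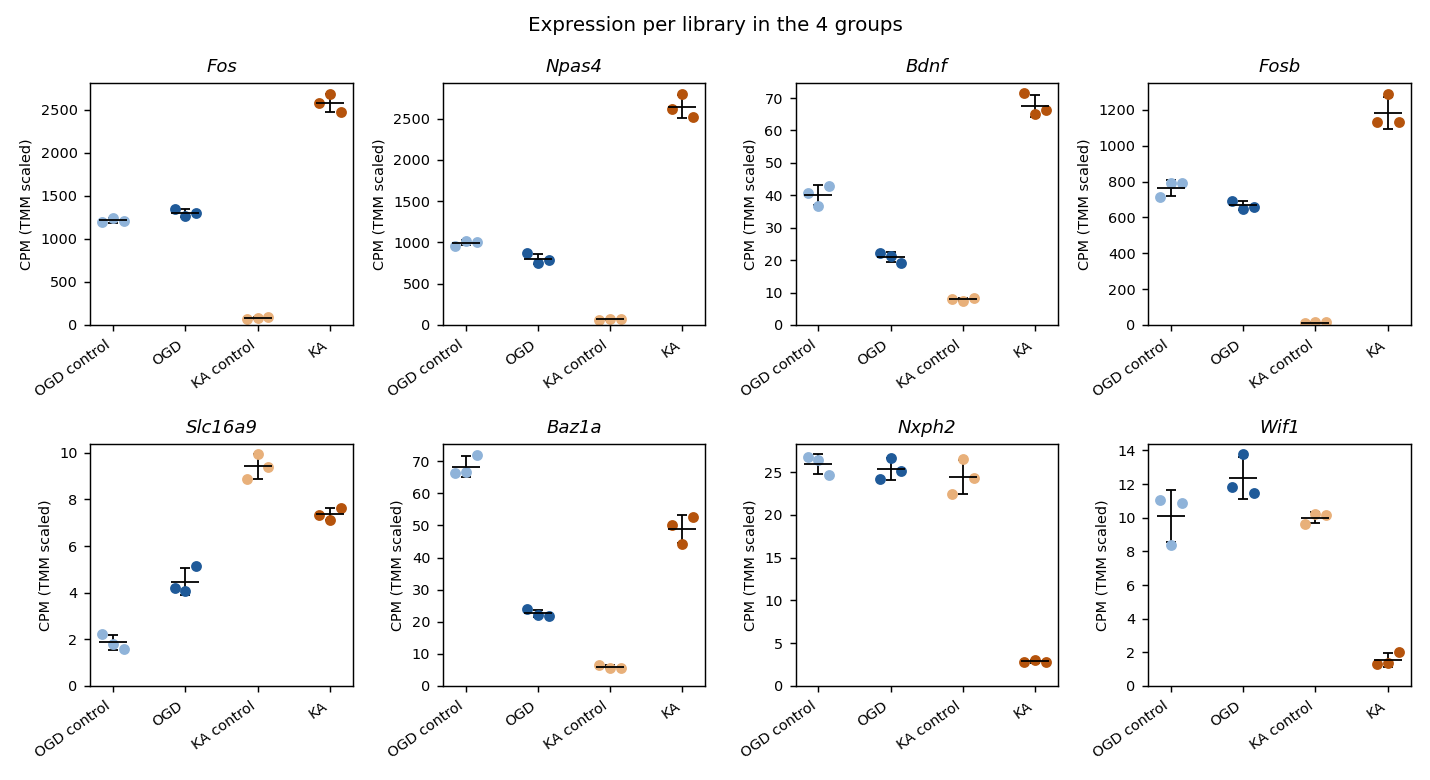
CPM of 8 genes in each library (dots), with the mean and SD of the 3 libraries per group (bars), for OGD control, OGD, KA control and KA. Fos, Npas4, Bdnf and Fosb are lowest in KA control and highest in KA, with both OGD groups between; Nxph2 and Wif1 are low in KA alone.

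Late activity-regulated genes followed, with 29 of 31 higher and 1 lower (median 1.97; the same counts adjusted over the list alone). Pcsk1, a prohormone convertase, and Nptx1 rose by 3.55 and 3.71 on the log2 scale, and Bdnf rose from 7.90 ± 0.55 to 67.6 ± 3.43 CPM. The list passed with both correlations (adjusted p = 2.06e-44 and, with an estimated correlation, adjusted p = 0.000691). Against OGD control, 17 of its 31 genes were higher in KA and 9 lower (median 0.29). Arc was counted at 3.16 ± 0.43 CPM in KA and at 0.081 ± 0.023 CPM in KA control, close to the smallest count that can be seen. Genes linked to axon injury rose in 20 of 26 cases and fell in 2 (22 and 3 adjusted over the list alone). Atf3 rose from 7.05 ± 0.47 to 192 ± 9.40 CPM. Jun, also in the immediate early list, and Galr1 rose by 3.90 and 4.86 on the log2 scale. Against OGD control, 14 of the 26 axon injury genes were higher in KA and 3 lower (median 0.24). Targets of p53 rose in 14 of 26 cases and fell in 3. Those with the smallest p were Btg2 (log2 fold change 4.65), also in the immediate early list, Plk2 (1.59), also in the late activity list, and Pmaip1 (2.21), which encodes the pro-apoptotic protein Noxa. Both lists passed with an estimated correlation (adjusted p = 0.0209 for axon injury and 0.0283 for p53 targets).

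Excitatory neuron markers rose in 13 of 15 cases after KA and none fell (median 0.86; 13 rose and 1 fell adjusted over the list alone; adjusted p = 3.66e-09, or adjusted p = 0.0283 with an estimated correlation). Nrn1, also in the late activity list, rose from 39.8 ± 4.59 to 420 ± 14.3 CPM and Fezf2 from 84.1 ± 3.33 to 460 ± 21.7 CPM. With OGD control in place of KA control, 11 of the 15 excitatory markers were higher in KA and 1 lower (median 0.42). Heat-shock chaperones rose in 14 of 20 cases and fell in 4, with Bag3 at 18.9 ± 2.18 against 1.31 ± 0.10 CPM and Hsph1 at 941 ± 32.2 against 421 ± 6.36 CPM. Ribosomal protein genes rose in 75 of 78 cases and fell in 1, by a median of 0.50; Rplp0 rose from 848 ± 18.1 to 1462 ± 124 CPM. Clock genes rose in 7 of 12 cases and fell in 2, with Per2 higher by 2.55 and Hlf by 2.46. General neuron markers rose in 9 of 17 cases and fell in 4; Nefl, the light neurofilament, rose from 395 ± 14.1 to 1517 ± 55.8 CPM. These 4 lists passed with the preset correlation (adjusted p = 0.00345, 3.1e-07, 0.000787 and 0.0231). With an estimated correlation none did (adjusted p = 0.426, 0.593, 0.111 and 0.398), and heat-shock chaperones also missed the threshold among the fewer genes with 1 annotated transcript (adjusted p = 0.0903, median 0.46 against 0.53).

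Of the lists of non-neuronal cell markers, that of astrocytes passed camera with the preset correlation after KA. Astrocyte markers rose in 8 of 14 cases and fell in 2 (adjusted p = 0.0464, or adjusted p = 0.426 with an estimated correlation), led by Sox9 at 50.7 ± 4.57 against 5.38 ± 0.84 CPM. That list missed the threshold without KA replicate 1 (adjusted p = 0.0556) or KA replicate 2 (adjusted p = 0.0578), and with the length trend removed (adjusted p = 0.0519). The other non-neuronal lists did not pass camera or were too short for it. Microglial markers rose in 7 of 9 cases (adjusted p = 0.538), at low levels: C1qb was 2.25 ± 0.50 CPM in KA and 0.81 ± 0.08 CPM in KA control. Endothelial markers rose in 3 of 3 cases, fibroblast and mural markers in 6 of 12 (adjusted p = 0.321), oligodendrocyte markers in 2 of 7, and blood and choroid plexus markers in 1 of 4 with 1 lower. Of inhibitory neuron markers 9 of 16 rose and 4 fell (adjusted p = 0.438). Among these, Sst rose by 1.24 on the log2 scale, while Nxph1 fell from 61.1 ± 2.52 to 14.1 ± 1.86 CPM. With OGD control in place of KA control, 14 of the 16 inhibitory markers were lower in KA and 1 higher (median -1.14).

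The genes that fell most after KA were led by Nxph2, a secreted ligand of neurexins, which fell from 24.4 ± 2.01 to 2.87 ± 0.15 CPM (log2 fold change -3.08, SE 0.11, adjusted p = 8.84e-21). Wif1, a secreted Wnt inhibitor, fell from 10 ± 0.34 to 1.55 ± 0.39 CPM (log2 fold change -2.72, adjusted p = 6.25e-15). The others were 2410018M08Rik (-2.99), Parp16 (-2.77), C330018D20Rik (-2.62), Alg6 (-2.62), Cep83os (-2.60) and Zmat1 (-2.47). Pro-apoptotic genes fell in 12 of 22 cases and rose in 5, with Bid and Bbc3 lower by 1.58 and 1.36 and Pmaip1 higher (camera adjusted p = 0.386). Metabotropic glutamate receptors fell in 5 of 6 cases and none rose (adjusted p = 0.125). Fosb lies on chromosome 7 at 19302696 to 19310051, Npas4 on chromosome 19 at 4984355 to 4990316 and Nxph2 on chromosome 2 at 23321246 to 23401973 (mm10).

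The remaining lists did not pass camera after KA. Ionotropic glutamate receptors went both ways (8 of 23 rose, 7 fell): Grin2a rose by 1.99, Grik3 fell by 0.22 and Grik5 rose by 0.19 on the log2 scale, and Grik4 did not pass (-0.01, SE 0.09). Grik1 (adjusted p = 0.0203) and Grik2 (adjusted p = 0.00999) had under 2 CPM in both KA groups and lost their calls when single libraries were left out: Grik1 without KA replicate 2 (adjusted p = 0.0785), KA replicate 3 (0.0908) or KA control replicate 1 (0.119), and Grik2 without KA control replicate 3 (0.0542). Grik1 also lost its call with DESeq2 (adjusted p = 0.0512). Of the AMPA receptor subunits, Gria1 fell by 1.02 at a level of 1.09 ± 0.18 CPM in KA, Gria2 did not pass (0.01, SE 0.09), and Gria4 fell by 0.38 (adjusted p = 0.0052, or 0.0686 without KA control replicate 2). With the length trend removed Gria2 was called lower (-0.20, adjusted p = 0.0218), and without KA replicate 1 it was called higher (0.16, adjusted p = 0.0341). Gria3 had too few counts to be tested. Of the 23 tested ionotropic receptor genes, 12 have 1 annotated transcript. Some genes with several have few counts in this table, so a low level here need not mean low expression. Mixed directions were also seen for hypoxia genes (13 of 30 rose, 11 fell; Slc2a1 higher by 1.71 and Narf lower by 1.14), ATF4 targets (14 of 31 rose, 5 fell), ER chaperones (12 of 23 rose, 6 fell), oxidative stress genes (15 of 23 rose, 5 fell), GABA receptor subunits (6 of 14 rose, 7 fell) and cholesterol synthesis genes (11 of 23 rose, 9 fell). The same was true of voltage-gated channels (12 of 36 rose, 11 fell), calcium handling genes (9 of 24 rose, 5 fell), presynaptic genes (18 of 33 rose, 8 fell), autophagy and lysosome genes (15 of 28 rose, 7 fell), nuclear long non-coding RNAs (5 of 8 rose, 1 fell), cell-cycle genes (5 of 21 rose, 7 fell) and interferon-stimulated genes (5 of 12 rose, 2 fell). Adjusted over the list alone, 4 of 36 lists had other counts, by at most 3 members.

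A few lists lay next to the threshold after KA. Postsynaptic scaffold genes rose in 17 of 29 cases and fell in 6 (adjusted p = 0.0531); the list passed without OGD control replicate 1 or 3, KA replicate 3 or KA control replicate 1 or 3, with adjusted p from 0.0413 to 0.0486, and had adjusted p = 0.426 with an estimated correlation. Respiratory chain genes rose in 45 of 73 cases and fell in 12 (adjusted p = 0.0567), and passed without KA replicate 3 (0.0114), KA control replicate 2 (0.0472) or KA control replicate 3 (0.0423). The respiratory chain list had adjusted p = 0.81 with an estimated correlation. Both lists passed with the other size factors at the preset correlation (adjusted p = 0.0453 for each). Glycolysis enzymes rose in 11 of 18 cases and fell in 3 (adjusted p = 0.0567, or adjusted p = 0.593 with an estimated correlation), with Slc2a3 higher by 2.29. That list passed without KA replicate 3 (0.0413), among genes with 1 annotated transcript (0.0428) and without the length trend (0.0211). Inflammatory genes rose in 9 of 10 cases (adjusted p = 0.0567, or 0.0407 without KA control replicate 3), with Nfkbia higher by 2.07. Presynaptic genes passed among genes with 1 annotated transcript (adjusted p = 0.0294). The inflammatory and presynaptic lists each had adjusted p = 0.426 with an estimated correlation. In several lists that did not pass, the median, the mean and the test differed in sign. After OGD these were immediate early genes, ER chaperones, oxidative stress genes, p53 targets, calcium handling genes and interferon-stimulated genes. After KA they were ionotropic glutamate receptors, GABA receptor subunits, voltage-gated channels, cholesterol synthesis, interferon-stimulated and cell-cycle genes.

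**Figure D2:**
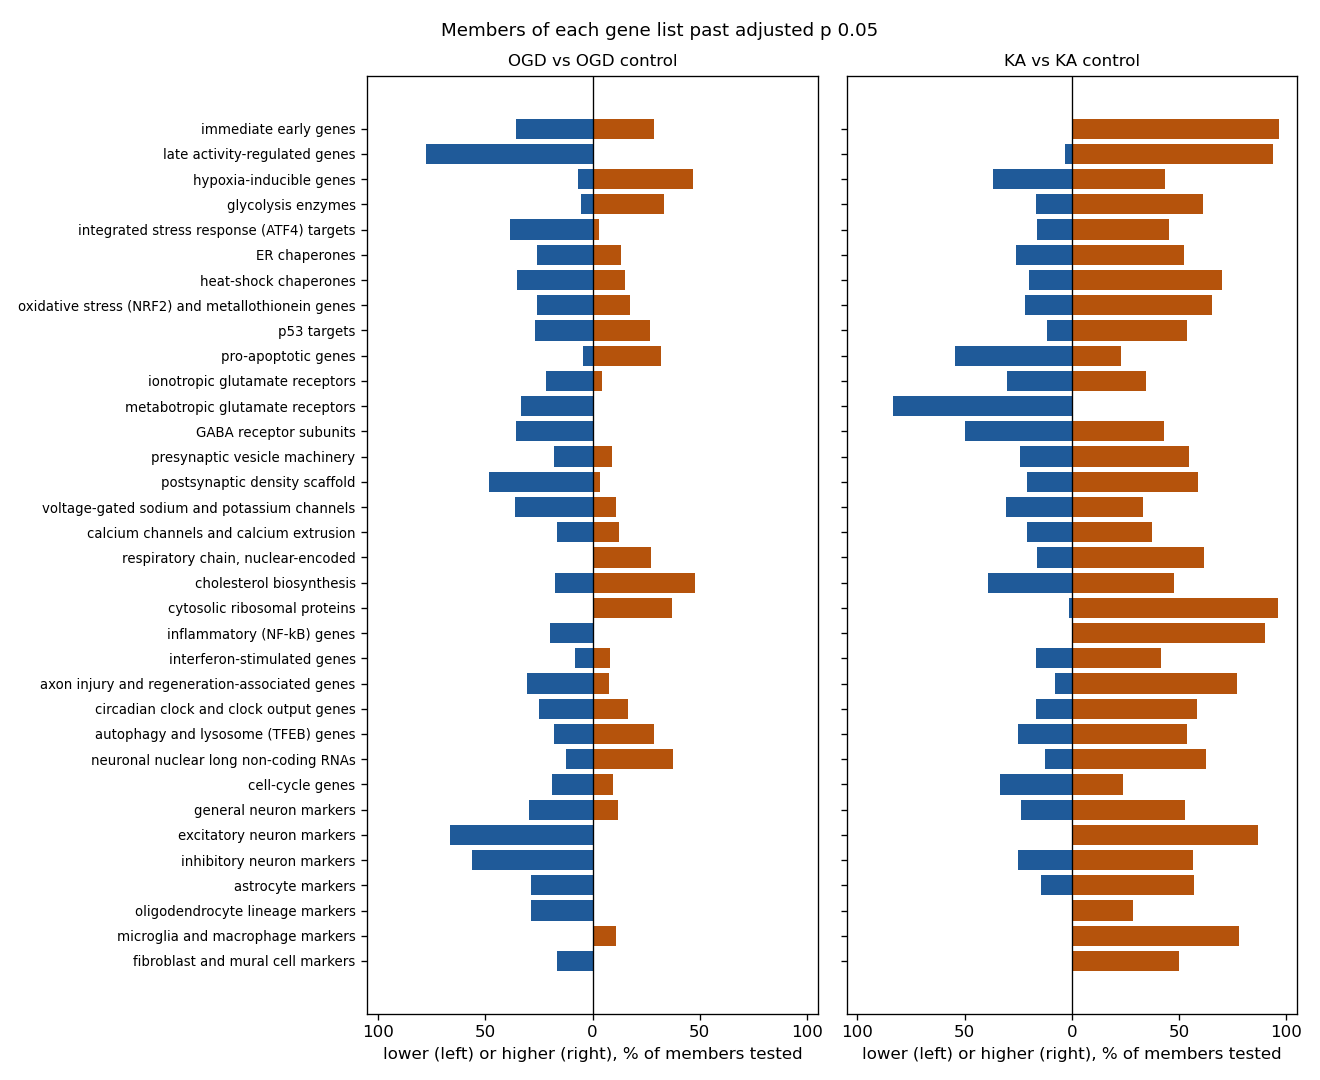
Share of the tested members of each gene list that was higher (right, orange) or lower (left, blue) past an adjusted p of 0.05, for OGD against OGD control and KA against KA control. The 34 lists with at least 5 tested members are drawn; immediate early genes reach 27 of 28 higher after KA, and late activity-regulated genes 24 of 31 lower after OGD.

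The effects of OGD and KA were then set against each other gene by gene. Activity-regulated genes separated them most: the difference of the responses was past the threshold in the KA direction for 27 of 28 immediate early genes (median -3.92) and 30 of 31 late genes (median -2.50). Fosb, Klf4, Gprc5a and Csrnp1 had the largest differences in that direction, at -6.65, -6.40, -6.29 and -6.18. Alg6 and Parp16 (3.24 each) led the genes that KA lowered and OGD did not. Both were high in KA control: Parp16 was 10.2 ± 0.94 CPM there, 2.09 ± 0.11 CPM in OGD control and 1.51 ± 0.30 CPM in KA, and Alg6 was 15.7 ± 0.65, 5.48 ± 0.87 and 2.56 ± 0.28 CPM. In all, 4516 genes responded higher to OGD and 4441 higher to KA. Of the genes tested, 445 rose and 523 fell in both comparisons, against 814.4 and 1012.1 for independent lists (odds ratios 0.379 and 0.329, Fisher's exact test, two-sided, p = 1.26e-75 and 1.14e-113). That test treats genes as independent, which they are not, so its p-values do not measure whether the overlap would recur in new cultures. Opposite calls were more frequent, with 1473 genes higher in OGD and lower in KA (869.7 for independent lists) and 1683 lower in OGD and higher in KA (947.7). The log2 fold changes correlated negatively across genes (Pearson's r = -0.357, Spearman's rho = -0.366, 13139 genes, which are not independent replicates). The comparisons shared no library.

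**Figure D3:**
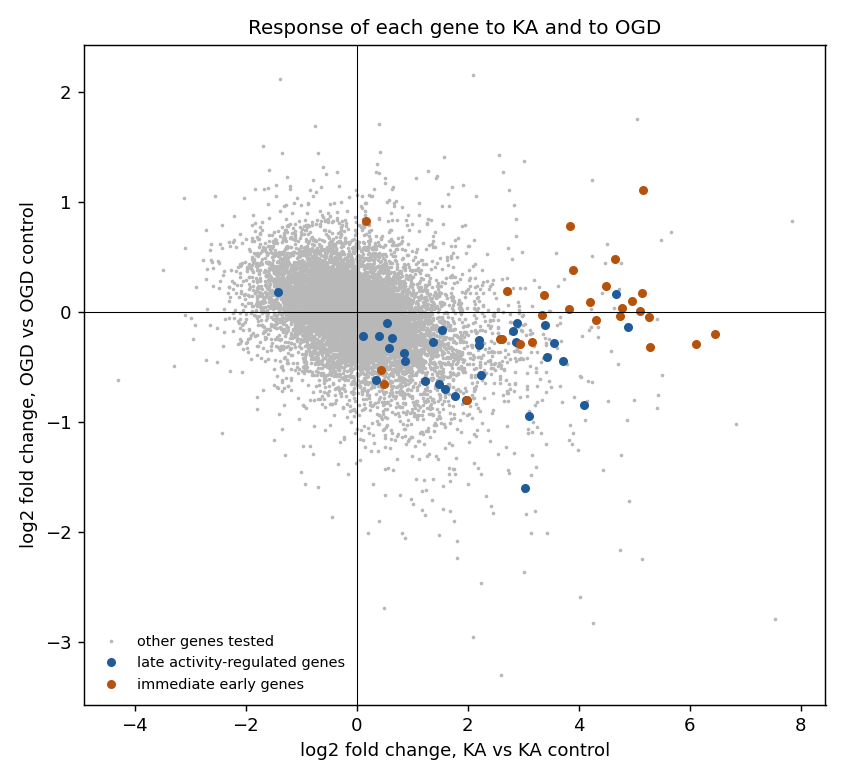
Log2 fold change of each of 13139 genes in KA against KA control (x axis) and in OGD against OGD control (y axis), with late activity-regulated genes in blue and immediate early genes in orange. The cloud slopes downward (r = -0.357), and nearly all coloured points lie to the right of 0.

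The untreated controls of the 2 experiments differed from each other about as much as KA differed from its control. Activity-regulated genes were far lower in KA control: Fos was 82.4 ± 8.75 CPM there and 1215 ± 27.3 CPM in OGD control, and 27 of 28 immediate early genes were lower (median -3.22; adjusted p = 1.14e-81, or adjusted p = 0.00305 with an estimated correlation). Late activity-regulated genes were lower in 28 of 31 cases, and Fosb (-5.82), Klf4 (-5.35), Gem (-4.67) and Slc15a2 (-4.57) had the largest differences. Inhibitory neuron markers were lower in 15 of 16 cases (median -1.49; adjusted p = 0.00305 with an estimated correlation), with Gad2 at 121 ± 2.15 against 653 ± 7.61 CPM. Presynaptic genes (25 of 33 lower, 2 higher) and axon injury genes (20 of 26 lower, 2 higher) also passed with an estimated correlation (adjusted p = 0.0229 and 0.0347). Ribosomal protein genes (72 of 78 lower) and respiratory chain genes (62 of 73 lower) passed with the preset correlation only (adjusted p = 0.563 and 0.504 with an estimated correlation). Of 16 lists past camera, all lower in KA control, 5 passed with an estimated correlation. Higher in KA control were 2410018M08Rik (2.36), Slc16a9 (2.36), Pus7l (2.33) and Parp16 (2.29). Over all genes, 4532 were higher and 4490 lower in KA control. OGD control libraries had a median Spearman correlation of 0.9803 with KA libraries and 0.9658 with KA control libraries, against 0.9914 with OGD libraries. All 3 control libraries of one arm come from a different experiment than those of the other, so differences between the experiments and between the control groups cannot be told apart.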

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

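The tests of scaling, exchanged libraries and cell mix reported here were chosen after the results were seen; the splits of the libraries were planned. The responses to OGD and to KA differed, by a test of the difference itself, for 8957 of 13139 genes. In the direction of KA the largest were Fosb (-6.65), Klf4 (-6.40), Gprc5a (-6.29), Csrnp1 (-6.18), Rrad (-6.05) and Galr1 (-5.84), and in the direction of OGD they were Alg6 (3.24), Parp16 (3.24), C330018D20Rik (3.10), Zmat1 (3.09), Cep83os (3.05) and Nxph2 (3.05). The gene lists that differed, all lower in the response to OGD, had median differences of -3.92 (immediate early genes), -2.50 (late activity-regulated genes), -1.33 (excitatory markers), -0.91 (axon injury), -0.74 (clock genes), -0.67 (astrocyte markers), -0.58 (p53 targets), -0.49 (heat-shock chaperones), -0.41 (postsynaptic scaffold), -0.41 (ribosomal proteins) and -0.31 (general neuron markers). With an estimated correlation 5 of these 11 passed: immediate early, late activity, excitatory, axon injury and p53.

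Of 100 splits drawn from 200 that regroup the libraries within each experiment, 1 gave as many genes with different responses, the real one; the highest other, with 7898, exchanged KA and KA control. The 7 other splits that kept the KA groups whole gave 6571 to 7898 genes and the other 92 at most 6, so the KA comparison carries most of this count. For calls in the same direction in both comparisons (968), 2 of 100 splits gave as many; the other was that same exchange, with 3156, which turns the opposite calls into shared ones. Splits that mix the KA groups remove the KA effect, so they say little about either count, and the 8 that keep these groups whole are too few for a share under 0.05. The shared calls were also fewer than the 814.4 and 1012.1 of independent lists, so a test for a large count does not bear on them. The 10 splits of 6 libraries are too few for a share under 0.05: only the real one reached the counts of 2315 and 2694 genes after OGD, 4622 and 4936 after KA and 9022 between the controls (1 of 10 each), and the highest other was 0. For the number of lists past camera the real value was 10 after OGD (1 of 10 splits, highest other 9) and 10 after KA (4 of 10 splits, highest other 14).

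Part of the contrast between OGD and KA lies in the controls, since activity-regulated genes were lower in KA control than in OGD control. Scaling between libraries is argued against, as immediate early genes lay -3.23 below the median of all genes. An exchange of OGD control with KA libraries is also argued against: every OGD control library correlated better with each OGD library than with any library of the KA experiment, by at least 0.0094. For the immediate early genes, a different mix of the cell types with at least 5 tested markers is argued against. The lowest median among those marker lists was -1.49 (inhibitory neurons) against -3.22. Endothelial and blood and choroid plexus markers were too few for this test, and cell types without a list were not covered. For the late activity-regulated genes, with a median of -1.65, a different mix of cells stays open. A culture batch or handling that differs between the experiments may be the source. The labels name 0 batches, dates or cultures, so it cannot be told apart from the experiment, and no biological explanation was tested.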

How the results depend on the processing

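The restriction to genes with 1 annotated transcript and the removal of the length trend were chosen after seeing the data. Gene counts stayed within 1.5 times of their values under every alternative run. Such totals do not show which genes were kept. With the length trend removed, 4144 of the 4957 OGD calls still tested were called with the same sign, and 8992 of 9432 KA calls. With the other size factors these were 4963 of 5009 and 9400 of 9558. With a library left out, genes higher in OGD ranged from 1818 to 2513 and lower from 2336 to 2858, higher in KA from 4433 to 4656 and lower from 4727 to 5001; different responses ranged from 8696 to 8956, differing controls from 8498 to 9252 and shared direction from 770 to 1054. Numbers of lists moved most: 2 after OGD and 5 after KA with an estimated correlation, and 21 and 32 with fry, which does not compare a list with other genes. Without the length trend 6 lists passed after OGD. Left-out libraries gave 9 to 10 lists after OGD and 9 to 13 after KA. For the list counts the cause was not tested. With the replicate block 11 lists passed after KA, the postsynaptic scaffold list among them (adjusted p = 0.0429, 0.0531 without the block). The block gave 2204 and 2630 genes after OGD and 4583 and 4900 after KA; same-number libraries correlated at 0.046, 0.026 and 0.026 in OGD and -0.044, -0.048 and -0.038 in KA, and the 6 OGD and OGD control libraries, but none of the 6 KA and KA control libraries, correlated best with their own number. All values lie under 0.1, so numbers were not taken to pair the libraries. Of 274 values of named genes the block changed no call, nor did other size factors; DESeq2 ended 5 calls and removal of the length trend 5. One gene changed direction: Gria2 in KA (0.01, not called) became -0.20 (called) without the length trend. Without KA replicate 1, Gria2 was instead called higher in KA (0.16, adjusted p = 0.0341). The cause was not tested. Depth limits genes under about 1 CPM.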

Other observations

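All families of gene symbols and the tests in this part were chosen after the data were seen. Across 52 families of symbols with at least 20 tested members, Rpl and Mrpl genes, of the large subunits of the cytosolic and the mitochondrial ribosome, went opposite ways after KA: Rpl genes rose in 42 of 45 cases and none fell, while Mrpl genes fell in 34 of 48 cases and 7 rose (medians 0.44 and -0.29; camera adjusted p = 0.00181 and 0.0215, or adjusted p = 0.719 and 0.616 with an estimated correlation). Mrps genes, of the small mitochondrial subunit, did not pass as a family after KA (17 of 29 lower, 4 higher, adjusted p = 0.0884). After OGD, 18 of 45 Rpl and 30 of 48 Mrpl genes were higher and 1 of each was lower (camera adjusted p = 0.00361 and 3.82e-05, or adjusted p = 0.797 and 0.298 with an estimated correlation). The families were not tested with the trend on transcript length removed. With it removed, the ribosomal protein list had a median of -0.0031 after OGD and did not pass camera (adjusted p = 0.67). Families that were lower after KA against its own controls at the preset correlation were beta protocadherins, neuronal adhesion genes in one cluster (20 of 21, none higher), zinc finger genes named Zfp (167 of 308, 71 higher), sorting nexins (22 of 29, 4 higher), Vps genes of vesicle sorting (22 of 30, 4 higher) Wdr genes (32 of 56, 15 higher) and centrosomal Cep genes (20 of 31, 4 higher). The smallest p belonged to Dusp genes, dual-specificity phosphatases, of which 11 of 21 rose and 9 fell (adjusted p = 1.98e-05), and Rps genes rose in 34 of 44 cases and fell in 8 (adjusted p = 0.0245). Families were formed by cutting symbols at the first digit, so the Rps family can hold genes that are not ribosomal proteins. In the ribosomal protein list 75 of 78 genes rose after KA and 1 fell. With an estimated correlation no family passed in any comparison; in KA the adjusted p was lowest for Dusp (0.347) and was 0.673 for Zfp. The KA controls already differed from the OGD controls in the opposite direction, with medians of 0.42 for Zfp (193 of 308 higher, adjusted p = 0.000101), 0.40 for Cep, 0.33 for Mrpl and -0.30 for Rpl.

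KA set against the OGD controls in place of its own had 25 of 28 immediate early genes higher and 1 lower, with a median of 0.89 on the log2 scale where its own controls gave 4.05. Late activity-regulated genes were higher in 17 of 31 cases and lower in 9 (median 0.29). OGD set against the KA controls had 27 of 28 immediate early genes higher and none lower (median 3.56), and 26 of 31 late genes higher and 3 lower (median 1.31), where its own controls gave a median of -0.29 for the late genes. In KA against OGD control the medians of excitatory markers, axon injury genes and p53 targets were 0.42, 0.24 and 0.43, where its own controls gave 0.86, 0.93 and 0.60. In OGD against KA control, 6 of 15 excitatory markers were higher and 6 lower (median 0.0040), where its own controls gave -0.30; axon injury genes and p53 targets had medians of 0.44 and 0.12. Inhibitory neuron markers, of which 9 of 16 rose against KA control, were lower in 14 of 16 cases against OGD control (median -1.14).

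Genes with several annotated transcripts had lower counts than the others in the lists tested for it. In the ribosomal protein and respiratory chain lists, 25 such genes had a median of 33.5 CPM and 128 genes with 1 transcript 224 CPM, a difference of -2.72 on the log2 scale (permutation test, two-sided, 100000 resamples, p = 1e-05, the smallest they can give). Loss to pseudogenes is argued against as the whole cause, since general neuron and presynaptic genes, which have few, differed by -5.49 (24 and 25 genes; the same p). Reads shared by transcripts of one gene may have been left uncounted; examples picked after their values were seen are Syt1 (0.92 CPM, 89 of 4827 bases in no other transcript) and Arc (1.43 CPM, 5 of 3057 bases). Across all 5711 genes with several transcripts the share of such bases correlated weakly with level (Spearman's rho = 0.13). Genes such as Lrrtm1 (2 transcripts, 345 CPM in OGD control) were well counted, so the cause stays a hypothesis for part of these genes. Fewer of the 5711 had no count at all (11.1% against 19.7% of genes with 1 transcript). Those shares include genes that neurons may not express, so they cannot decide the question.

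The rise of ribosomal protein and respiratory chain genes after OGD may be part of a trend on transcript length. In 5 bins of genes from the shortest to the longest, the median log2 fold change in OGD went 0.11, 0.05, -0.0040, -0.05 and -0.08. With the trend removed from each library, the medians of the lists went from 0.10 and 0.10 (SD across genes 0.09 and 0.08) to -0.0031 and -0.0039 (SD 0.09 and 0.07), and the calls ended because the medians moved to 0. Short transcripts are shared by many genes of these complexes (median exonic length 843 and 864 bases), so a real change in them and a length effect of library preparation remain open. RNA quality was not measured in the data used here.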
